A study of Ogataea haglerorum with 3 samples.

How the data were processed

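The series measured polyadenylated RNA by sequencing in Ogataea haglerorum, a haploid budding yeast. Cells were grown in rich glucose medium (YPD) at 30 °C to log phase, at an optical density (OD600) of 0.8 to 1.2, from an overnight culture of 16 h. The labels give 1 group of 3 libraries, numbered as replicates 1, 4 and 5, and no second condition. They describe libraries made with a Tecan mRNA-Seq kit and single-end sequencing on an Illumina instrument. The labels do not say that each library came from its own culture, so the spread between them may be technical. The tests below set counts against counting error or compare genes with each other, and none measures variation between cultures. The design text names a comparison with the related species Ogataea polymorpha, which was not analysed here.

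Per the file headers, the authors made the deposited counts with featureCounts 2.0.1, summarising reads over gene features of their own annotation with strand setting 1 and the paired-end option. The command carried no option to count multi-mapping reads. Per the submitters' processing notes, HISAT2 2.2.1, SAMtools, deepTools and HTSeq were also used, with no role given for any of them; HTSeq is named there although the header of the counts names featureCounts. The genome build behind the chromosome names was not given in the sources used here, and coordinates below are those of the authors' files. The deposited TPM values (TPM corrects for gene length and sums to a fixed total per library) are the authors' own. The deposited table held 5345 genes on 7 chromosomes, with 0 per-sample columns left unused.

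The files were checked against each other before use. All 5345 counts of each library were equal in the single-library file and the joint table. TPM recomputed from counts and lengths equalled the deposited TPM within 1% for 5298, 5302 and 5298 genes with a count in libraries 1, 4 and 5. Locus tags of the ASM1920728v1 assembly matched 5301 gene IDs and did not match 44, and 106 genes of that assembly had no row. The length was equal for 5243 of the matched genes (98.9%). That assembly was used only for which genes neighbour each other. It pairs 0 of its genes with a name other than the locus tag, so 0 of the 24 gene lists fixed beforehand could be matched and the planned test of gene list levels was not run. Genes that share reads with a near-identical copy are uncertain, since no sequence was used here, and 3 neighbouring pairs of genes overlapped.

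Total counts over genes were 34047362, 44734719 and 34526996 in libraries 1, 4 and 5. A count of 0 allows a level of up to 3 counts, which is 0.0881, 0.0671 and 0.0869 CPM (counts scaled to the library total). Floors cover only the counting error of reads assigned to a gene, and reads amplified by PCR are not independent molecules. Exact binomial intervals below are over numbers of genes and cover no counting error of reads. They take genes as independent, although neighbouring genes were weakly alike.

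Replicates were compared by chi-square of their counts against Poisson sampling, by Pearson r of log2(CPM + 1) and by Spearman rho across genes. The common dispersion came from edgeR 4.0.16 in R 4.3.3, with TMM scaling and its filter on low counts, and is given as the biological coefficient of variation (BCV). DESeq2 1.42.0 gave an alternative. Genes varying between replicates were tested among genes with a mean CPM of at least 10, by chi-square of the counts beyond sampling noise with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a highest-to-lowest CPM ratio of at least 2. A gene was detected with at least 10 counts in each library.

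Position was measured from the gene edge farther from the nearest chromosome end. Chromosome lengths were not given in the sources used here, so the left end is base 1 and the right end is the last base of the last annotated gene; true distances on the right are longer by an unknown amount. Genes within 20 kb of an end are called subtelomeric and all others internal. Levels were compared as medians of log2(TPM + 1), which understates differences of low genes. The two-sided permutation test drew 100000 random sets of genes. A second test rotated the values along the genome through all 5345 positions, which keeps neighbours together. Neighbouring genes were compared by Spearman rho with the gene order shuffled 10000 times. Genes are not independent replicates, so these p-values describe the arrangement of genes in these libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

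The statistics were tested on simulated data. For the replicate spread, BCVs of 0.05, 0.1 and 0.3 were simulated for 5345 genes, with the same value for all genes of a simulation. The estimates, made after the filter on low counts, were 0.0503, 0.100 and 0.294. Unequal spread between genes was not simulated. For genes varying between replicates, genes changed 1.5-fold were called in 0% of cases, 2-fold in 62% and 3-fold or 4-fold in 100% (50 genes each), and 0 of 4372 unchanged genes were called. These counts were drawn with Poisson noise alone, without the further spread seen between the real libraries. The 0 calls among unchanged genes thus cover counting error only, and the 0% at 1.5-fold follows from the required 2-fold ratio. For the subtelomeric comparison, 8% of 200 random null sets fell under 0.05. A repeat with other seeds gave 6.6% of 1000 sets, and a larger run, its size and seed fixed beforehand because the first runs lay above the nominal rate, gave 4.97% of 10000 sets. Another repeat of 1000 sets, made between the first and these runs with the original seeds replaced, was set aside and its value is not given. An implanted shift of -1 was recovered as -1, which follows from how it was added and tests nothing. The null sets were full shuffles of the genes. They thus do not show how the permutation test behaves where neighbouring genes are alike.

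The groups, planned tests, alternatives and the rule for named genes were fixed before the data were examined, except where the closing section says otherwise. That plan did not include Fisher's exact test on low counts near the ends, nor the tests of distance bins and of differences between ends. Tests of single chromosomes and of divergent against convergent neighbours were also outside it. Without gene names, the rule for named genes prints at most 2 IDs among the highest genes and 2 among the varying genes. Other genes are given by position. Alternatives covered the scaling, the filters, the pseudocount, the distance from the end, the strand of neighbours, depth (by thinning to the shallowest library and to 10% of the counts), and leaving out each replicate.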

Results

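Transcript levels were measured in log-phase Ogataea haglerorum, a methylotrophic yeast, by sequencing of polyadenylated RNA in 1 group of 3 libraries. The design text gives the purpose as an assessment of gene expression in this species, and the series title concerns a translocation, subtelomeric chromatin and genome organization. The libraries held 34047362, 44734719 and 34526996 counts over 5345 genes for replicates 1, 4 and 5. The median gene had 2167, 2820 and 2183 counts. Median TPM was 53.0, 51.2 and 52.5.

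Nearly the whole annotated gene set was detected. Background outside genes was not measured, so a few counts do not establish that a gene was transcribed. At least 10 counts in each library were found for 5170 genes (96.7%), and 5017 genes (93.9%) had a TPM of at least 1 in each. The 175 genes below 10 counts in at least 1 library lay disproportionately near chromosome ends. They made up 45 of the 147 genes within 20 kb of an end (30.6%) and 130 of the 5198 internal genes (2.50%), an odds ratio of 17.2 (Fisher's exact test, two-sided, p = 4.51e-33). The test takes genes as independent, but levels of neighbouring genes were weakly alike, so the p-value can be too small. No count in any library was found for 16 genes, 5 of them subtelomeric. This bounds the reads assigned to them at the floor of 3 counts per library. A gene with a near-identical copy could have a higher level, since no option to count multi-mapping reads was set. A mean TPM under 5 was found for 571 genes (10.7%) and one over 1000 for 179 genes (3.35%).

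Expression was concentrated in few genes. The 10 highest genes held 8.71% ± 0.50 of TPM, the 100 highest 38.3% ± 0.38 and the 500 highest 66.5% ± 0.27 (SD, n = 3). The highest gene was KL911_002259, on the plus strand of chromosome 6 at 84568 to 85583, with 13300 ± 1039 TPM (SD, n = 3), 255-fold over the median gene. KL911_002185, on the minus strand of chromosome 6 at 210940 to 211947, followed with 11734 ± 1599 TPM. The 20 highest genes spanned 4754 to 13300 TPM on 6 chromosomes, and their SD ranged from 0.888% to 30.5% of the mean. Of the 100 highest genes, 0 were subtelomeric, which was not tested against the 147 such genes among 5345. Their median length was 584 bases, against 1209 for the other genes. Ranked anew by counts, without correction for length, the 100 highest genes held 30.4% ± 0.42 of counts. That set need not hold the same genes.

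Genes near the chromosome ends had far lower TPM than the other genes, and the series title names subtelomeric chromatin. TPM rests on reads assigned to annotated genes. Wrongly predicted genes and reads lost to copies of unequal length or elsewhere in the genome stay open as causes. The 147 subtelomeric genes had a median of 1.89 ± 0.18 TPM and the 5198 internal genes 54.1 ± 0.85 TPM (SD, n = 3), a 28.6-fold difference. Under 5 TPM lay 98 subtelomeric genes (66.7%) and 473 internal genes (9.10%). On the log2(TPM + 1) scale the subtelomeric median differed by -4.25 ± 0.07 from the internal one (SD, n = 3), with the libraries between -4.33 and -4.20. With each gene averaged over libraries first, the difference was -4.36. The permutation test gave p = 1e-05, the smallest it can give, and rotation of values along the genome gave p = 0.000561. Median gene lengths were similar, at 1284 and 1194 bases.

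The low levels faded with distance from the end. The median was 0.738 TPM in the outermost 10 kb, 2.88 TPM from 10 to 20 kb, 9.30 TPM from 20 to 30 kb and 21.7 TPM from 30 to 40 kb. Genes over 100 kb from an end had a median of 55.3 TPM. Against those genes the log2 differences of these 4 bins were -5.03 ± 0.06, -3.87 ± 0.17, -2.52 ± 0.06 and -1.32 ± 0.09 (SD, n = 3; permutation test, adjusted p = 0.00025 for each). From 40 to 50 kb the median was 41.4 TPM, a difference of -0.41 that did not pass the test (permutation test, adjusted p = 0.101).

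**Figure D1:**
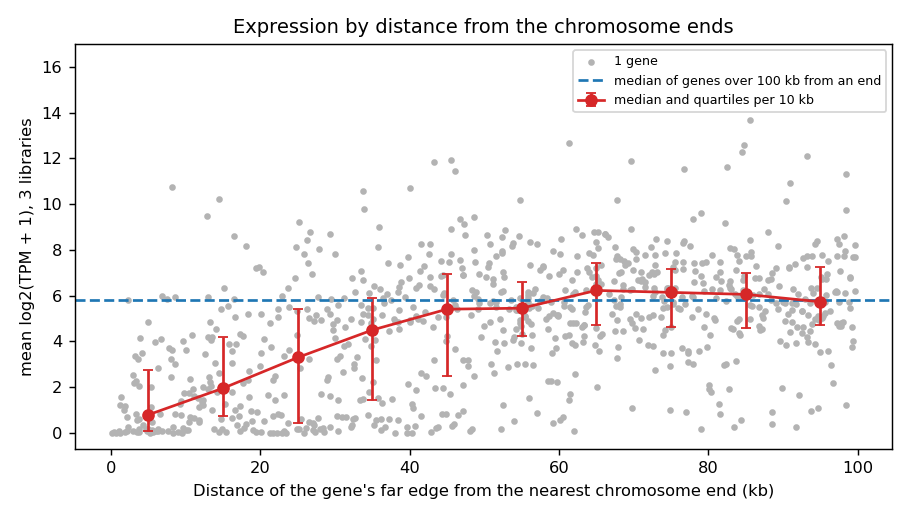
Mean log2(TPM + 1) of 3 libraries on the y axis against the distance in kb of each gene's far edge from the nearest chromosome end on the x axis. Grey points are genes, red points with bars are medians and quartiles per 10 kb, and the dashed line is the median of genes over 100 kb from an end; the medians in TPM rise from 0.738 in the first 10 kb to 41.4 at 40 to 50 kb.

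Each of the 14 chromosome ends had a median below that of the internal genes, but the medians of the ends were unequal (Kruskal-Wallis H = 31.3, permutation p = 0.0017). The permutation shuffled single genes between ends. Neighbouring genes were weakly alike and levels rose with distance, so the test cannot show that the ends differ beyond these effects. Ranked by median TPM, the lowest was the left end of chromosome 6, at 2072 to 18868, whose 7 genes had a median of 0.0705 ± 0.0093 TPM (SD, n = 3) and all lay under 5 TPM. The left end of chromosome 7 followed with 0.370 ± 0.219 TPM, the left end of chromosome 3 with 0.448 ± 0.116 TPM, the right end of chromosome 1 with 0.476 ± 0.019 TPM and the right end of chromosome 7 with 0.486 ± 0.084 TPM. From the left end of chromosome 6 on, 5 of 7, 4 of 8, 4 of 10, 5 of 12 and 5 of 10 genes had under 10 counts in at least 1 library. These medians thus rest on few counts, and the order of these ends was not tested. The highest was the left end of chromosome 5, at 1557 to 19421, with 10.6 ± 0.31 TPM over 12 genes, followed by the right end of chromosome 6 with 9.95 ± 1.76 TPM. On the log2(TPM + 1) scale of gene means these 2 changed places, with medians of 3.19 and 3.44, as did the right ends of chromosomes 1 and 7, with 0.58 and 0.54.

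Some subtelomeric genes were well expressed. Of the 147, 14 lay above the internal median (9.52%, exact 95% binomial interval 5.31% to 15.5%) and 7 exceeded 100 TPM. The highest lay on chromosome 4 at 7031 to 8188, with 1727 ± 67 TPM (SD, n = 3), and on chromosome 2 at 1439919 to 1440941, with 1201 ± 29 TPM. A gene on chromosome 1 at 942704 to 943747 reached 775 TPM with an SD of 348, and was among the genes that varied between replicates.

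**Figure D2:**
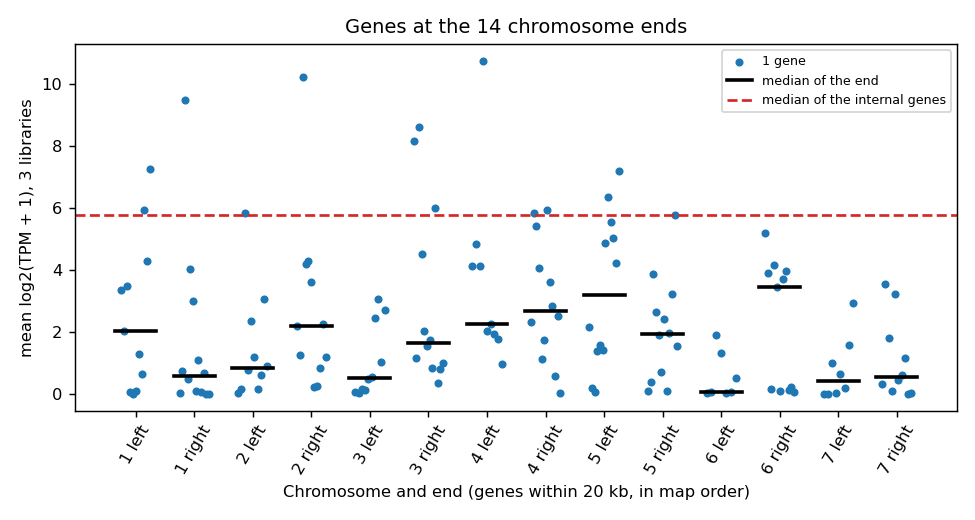
Mean log2(TPM + 1) of 3 libraries on the y axis for each gene within 20 kb of the 14 chromosome ends, which stand along the x axis. Points are genes, black bars the median of each end and the dashed line the internal median; all 14 bars lie below the line, and single genes such as that of 1727 TPM on the left of chromosome 4 lie above it.

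Levels were weakly alike between neighbours along the chromosomes. Spearman rho between adjacent genes was 0.189 ± 0.003 (SD, n = 3 libraries; 5338 pairs; permutation p = 0.0001, the smallest it can give). Same-strand pairs gave 0.180 and opposite-strand pairs 0.198. Without genes within 50 kb of an end rho was lower, 0.118 over 4946 pairs.

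**Figure D3:**
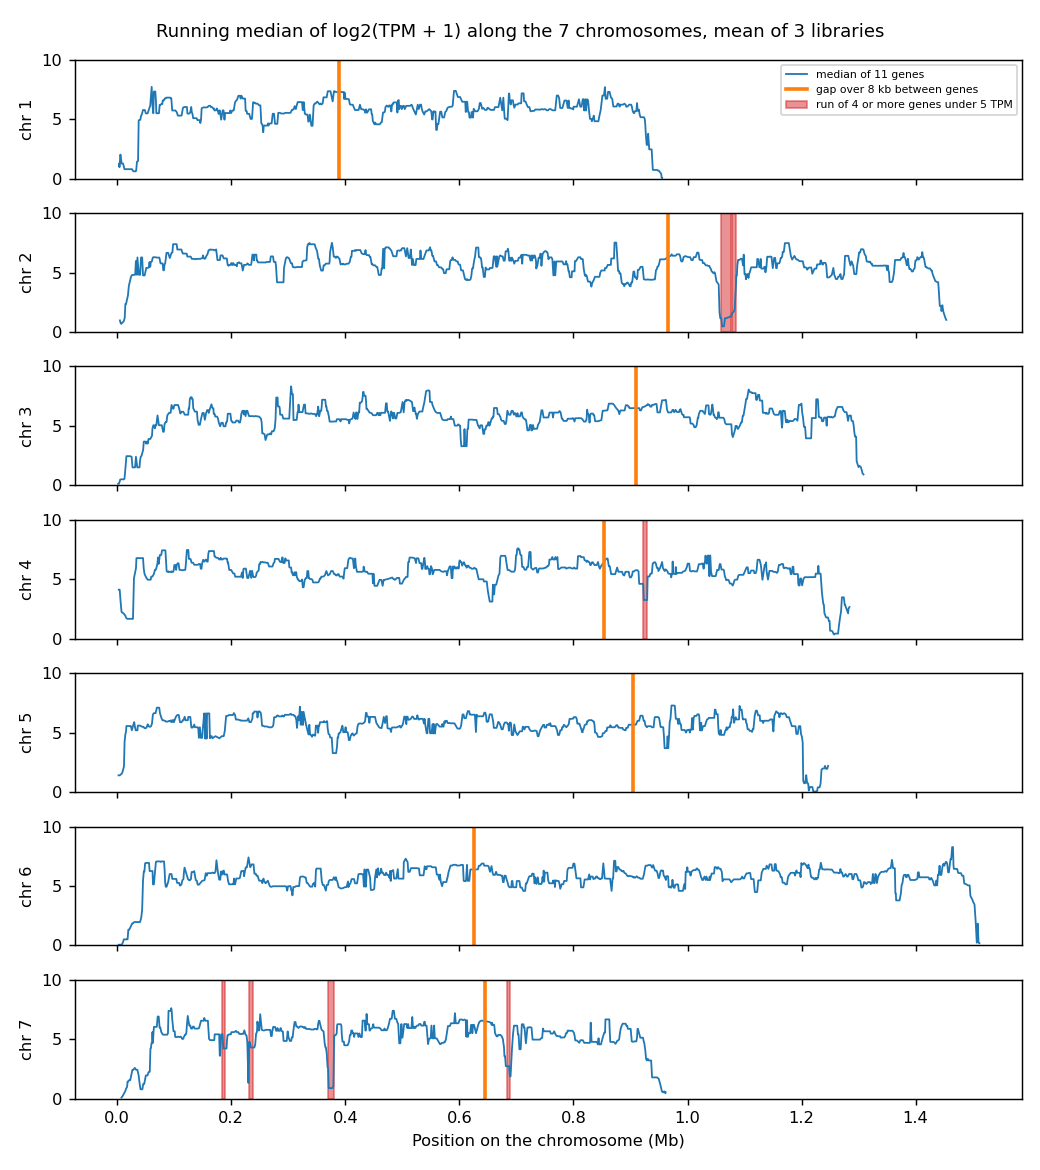
Running median over 11 genes of log2(TPM + 1), mean of 3 libraries, on the y axis against position in Mb on the x axis for each of the 7 chromosomes. Orange lines mark gaps of over 8 kb between genes and red bands runs of 4 or more genes under 5 TPM over 50 kb from an end; the profile drops towards the ends of each chromosome.

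The libraries resembled each other closely but differed beyond counting error. Pearson r across genes was 0.996 for replicates 1 and 4, 0.995 for 1 and 5, and 0.994 for 4 and 5. The chi-square per degree of freedom was 33.3, 64.4 and 101, so no pair agreed within sampling noise, as the same library deposited again would. The median gene differed 1.07-fold, 1.09-fold and 1.09-fold. The BCV was 0.108.

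Few genes varied strongly between replicates. Of 4578 genes tested, 3729 (81.5%) exceeded counting error at an adjusted p under 0.05, and 28 (0.612%) also differed at least 2-fold. Replicate 5 was lowest for 24 of the 28 and replicate 4 highest for 23. KL911_002717, on the plus strand of chromosome 1 at 878309 to 879982, had 5.43, 76.1 and 9.66 CPM in replicates 1, 4 and 5, from 186, 3375 and 334 counts, the highest ratio of highest to lowest CPM among the 28. The divergent gene on its left, at 876801 to 878036, had 9.95, 20.3 and 10.6 CPM, while the gene on its right, at 880042 to 881160, differed 1.06-fold. KL911_004133, on the minus strand of chromosome 7 at 937158 to 938447, had 132, 237 and 75.2 CPM. Without replicate 5, 5 genes passed, and without replicate 4, 9 passed.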

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

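Chosen after seeing the data were the settings on long genes, left or right ends, single chromosomes left out, the 2 thinnings of the subtelomeric comparison, and removal of genes within 50 kb of an end. The subtelomeric difference kept its direction and its side of the threshold under all 22 settings, from -4.96 within 10 kb to -2.45 with a pseudocount of 10. It was -2.81 within 50 kb, -3.76 among genes with 10 counts or more, and -4.49 with 10% of the counts. Neighbouring genes stayed positively correlated under 8 settings, from 0.118 without the ends to 0.198. Detected genes numbered 4972 to 5266 under 7 settings; thinning to the shallowest library (5164 genes) does not show what more depth would add. The BCV ranged from 0.0852 to 0.128 when 1 replicate was left out. The 100 highest genes by counts held 30.4% of counts, and the 100 highest by TPM held 38.3% of TPM. Counts carry no length correction, and the genes were ranked separately for each measure. The count of varying genes depended most on the settings. It was 218 with no filter beyond 1 count, 12 at a mean CPM of at least 50, 174 at a ratio of at least 1.5 and 3729 with no minimum ratio, as the construction of these settings implies. Leaving out 1 replicate gave 5 to 23 genes, with 5 without replicate 5 and 9 without replicate 4. Median-of-ratios scaling called the same 28 genes, and library totals called 29, of which 28 were shared. The planned gene list levels were not run, because no list could be matched to the gene IDs. No paired analysis was possible because the labels give 1 group.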

Other observations

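The tests on the gaps between genes, on runs of low genes, on scaling and nearness to an end of the varying genes, and, near the ends, on short genes alone and thinning to 10% of the counts were chosen after the results were seen, as was the bound applied to the planned setting of 10 counts or more. Away from the ends, genes of low level also stood together. Among 4953 genes over 50 kb from an end, 385 (7.77%) had under 5 TPM, and 7 runs of at least 4 such genes held 41 of them. The longest run held 10 genes on chromosome 2 at 1058810 to 1075862, with a median of 0.823 TPM, and was parted from a run of 4 at 1077391 to 1085120 by 1 gene at 70.0 TPM. The next held 8 genes on chromosome 7 at 369392 to 379590, and 4 of the 7 runs lay on chromosome 7. With the genes shuffled, the longest run had a median of 3 and a highest of 6 genes, and a run of 10 had a share of 0.0001, the smallest the shuffles can give.

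Chromosome 7 had the lowest median level, 43.0 ± 1.28 TPM (SD, n = 3), while the other chromosomes lay between 49.2 and 54.8 TPM. Its log2 difference from the other chromosomes was -0.32 (permutation test, adjusted p = 0.0056 over 7 chromosomes, and rotation p = 0.00505, run for chromosome 7 alone and not adjusted). Without genes within 50 kb of an end it was -0.24 and did not pass (permutation test, adjusted p = 0.0728). Without the low runs as well it was -0.153 (permutation p = 0.137), which lay between the bounds set beforehand and decided nothing. Divergent neighbours had a rho of 0.235 and convergent neighbours 0.161 (permutation p of the difference = 0.0433), and over 50 kb from the ends the difference was 0.0763 (permutation p = 0.0453).

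The low level of subtelomeric genes was weighed against technical explanations. Short genes as the whole cause were argued against by a difference of -4.21 among the 79 subtelomeric genes at least as long as the median gene, but length does not show whether a gene model is right, so wrongly predicted genes stay open. Loss of reads to copies of the same length at other ends was argued against by a share of 14.3% of the 98 low genes with such a partner (exact 95% binomial interval 8.04% to 22.8%; random internal sets had a median of 12.2%). Lack of counts as the whole cause was argued against by -3.76 among the 120 subtelomeric genes with 10 counts or more; a contribution of depth was not decided, since thinning to the shallowest library (0.000929) left library 1 whole and thinning to 10% of the counts moved the difference by 0.125, between the bounds of 0.1 and 0.5. Copies of unequal length or elsewhere in the genome stay open, since no sequence was used, and no biological explanation was tested.

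Each chromosome had exactly 1 gap of over 8 kb between neighbouring genes, from 8018 to 10766 bases, while the next longest gap was 4872 bases. Random placement of 7 gaps put 1 on each chromosome in a share of 0.00546. A join between assembly pieces on chromosome 2 was argued against by 1 gap there whose flanking genes are consecutive in the other assembly; 4 further gaps had both flanking genes in that assembly without being consecutive, so a join stays open for these and for the 2 gaps with an unmatched flank. A candidate explanation is that the gaps hold centromeres, which was not tested and which no label gives. The 70 genes within 5 of a gap had a median of 84.6 TPM, 0.61 above the other genes over 50 kb from an end on the log2 scale (permutation p = 0.0165; rotation that keeps neighbours together, p = 0.0412).

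The 28 genes varying between replicates were mostly lowest in replicate 5, and 23 were highest in replicate 4. Replicate 5 was lowest for at least 85.7% of the genes called under each of 3 scalings, but these differed by up to 0.985% for that library. The 95th percentile of the ratio over all tested genes, 1.46 with library totals, was fixed by the few genes called. Neither value thus decides whether the scaling of replicate 5 is the cause. A factor moves all genes alike, and the median ratio of the 4577 genes tested with library totals was 1.13. If most genes kept their level, this argues against 1 wrong factor for replicate 5 as the whole cause of 2-fold differences. Without replicate 5, 4 of the 28 were still called, which no factor for that library can produce. For the others, a part played by a smaller factor stays open. Genes within 50 kb of an end were 5 of the 28 (17.9%) and 185 of the tested genes (4.04%), an odds ratio of 5.28 (Fisher's exact test, two-sided, p = 0.0047). The test takes genes as independent, but those at 931218 to 932300 and 937158 to 938447 on chromosome 7 lay close together at the same end. Nearness to an end may go with part of the variation. The culture, harvest and library of replicates 4 and 5 stay open, and no biological explanation was tested.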
